A study of Mus musculus with 6 samples.

How the data were processed

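Single-cell RNA was measured in 6 libraries of mouse neural tube organoids grown from embryonic stem cells that carry reporters of Sox1 and of T (Brachyury). Per the submitters' notes, single cells were embedded in Matrigel, cultured with basic fibroblast growth factor and activin-A until day 3 and without them afterwards, and organoids kept beyond day 6 were moved to fresh Matrigel, 1 per drop. Organoids were dissociated with TrypLE, and libraries were made with the 10x Genomics kit for 3 prime ends. The submitters name Cell Ranger 3.1 and the mouse build mm10. The authors filtered the cells and assigned the cell classes, and how they did so is not stated in the labels.

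The authors deposited 2 tables. The day 6 table holds the non-elongated library and elongated replicate 1, with 18144 genes and 4301 cells. The other table holds elongated replicate 2 and the day 7, day 8 and day 10 libraries, with 21062 genes and 11981 cells. The values in the deposited matrices are UMI counts per gene and cell, with no normalisation. The authors' metadata give the UMI counts and detected genes per cell as counts, and the mitochondrial share in percent. All 16282 cells are accounted for: the column sums and detected genes were checked against the metadata and matched in every cell. The cells of the day 6 table range from 3502 to 7498 detected genes per cell with at most 7.49% mitochondrial UMIs. In the other table they range from 3002 to 9993 genes with at most 9.97%. The 2 tables thus passed different filters. The day 6 table names its libraries NENT and SENT; these were read from their initials as non-elongated and elongated, and the labels do not spell them out. The deposited columns of class names, library names, barcodes and gene symbols are names and carry no unit (other).

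UMIs were summed over all cells of a library, because cells of 1 library are not replicates. Only the 17296 gene symbols present in both tables were compared; 848 symbols are in the day 6 table alone and 3766 in the other alone. Counts were tested in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1: TMM scaling, filterByExpr with a minimum count of 10, a quasi-likelihood fit with a separate mean for each of the 5 groups, and Benjamini-Hochberg adjustment with a threshold of 0.05 on the false discovery rate (FDR). This tested 16379 genes. All adjusted p-values in the text are from edgeR unless DESeq2 is named. The fit has 1 residual degree of freedom, which comes from the elongated day 6 duplicates, so every lone library is assumed to vary as they do. The common dispersion was 0.0872, which edgeR terms a biological coefficient of variation, of 29.5%. The duplicates carry different batch labels and lie in different tables. Differences of batch and table are therefore part of this spread and enter every adjusted p-value. A term for the table could not be added beside 5 group means. In data simulated from these counts, 100 genes given a 4-fold change were called in 38% of cases for the non-elongated comparison and in 81% for day 10, with 0 and 5 false calls. Genes given a 2-fold change were called in 0% and 6%. The simulation drew every library from the elongated day 6 means, with a spread set by abundance alone. Only abundant genes were changed, and only in the compared group. Its rates are therefore not those of the reported tests. The same test was run on the neural progenitors alone (15789 genes).

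Expression is given in CPM (UMIs scaled to a common library total, with TMM factors). Log2 fold changes of genes against the pooled duplicates are from the fit. Their standard error (SE) is the size of the log2 fold change over the square root of its F statistic. Log2 values against 1 replicate alone and list medians are differences of log2 CPM with a prior count of 2. Medians within or set beside single cell classes add 1 CPM to each side instead. Where a fold is printed, it is the ratio to the mean of the elongated day 6 duplicates. Where a group had 0 UMIs, the fold is a lower bound against a floor of 3 UMIs in that library. List medians with such genes at their bound leave out members with 3 UMIs or fewer in both groups. Values per cell class are CPM without TMM factors. A count of genes at least 2-fold apart, with a prior count of 2, has no test and is set beside the same count between the duplicates, which also differ in table. Shares of cells are given with exact (Clopper-Pearson) 95% intervals, which cover counting error only. The authors' classes were also grouped as neural progenitor, neuron, neural crest, epiblast, surface ectoderm and mesenchyme. Cells with a UMI of both T and Sox2 were counted after thinning each cell to 5000 UMIs.

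The genes named in the text follow a rule. For the non-elongated and day 10 comparisons, it took the 10 highest and 10 lowest log2 fold changes among called genes with at least 20 CPM in the higher group and the same sign against each duplicate. Where fewer were called, it was filled with uncalled genes of the same kind whose difference exceeded that between the duplicates. It took 5 each way for day 7, day 8 and the progenitors, up to 4 members of each list by FDR, and 10 fixed genes, of which Shh is not analysed here. Gene lists numbered 40, including 15 of cell type markers, and 38 had at least 3 measured members. Each list's median log2 fold change was ranked among 10000 random lists of equal size and similar expression, and the ranks themselves are not printed. Counts of risen or fallen members stand beside 654, 2192 and 4320 of 16379 genes called at day 7, day 8 and day 10. A list whose share of called members is near that over all genes does not stand out. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined.

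Alternatives were DESeq2 1.42.0, other scalings (RLE, library size alone), no filter and a minimum count of 100, day as a linear term (3 residual degrees of freedom), leaving out each duplicate, leaving out doublets called by Scrublet, thinning to the shallowest library, a prior count of 10, equal cell numbers (2076 per library) and clusters made over all 6 libraries with scanpy 1.11.5 (2000 variable genes, 30 principal components, Leiden resolution 1). Alternatives without genes that share exons with another gene, with 176 renamed symbols joined, and with progenitors and epiblast together were chosen after the data were seen. Exons and coordinates came from GENCODE vM21 on mm10, in which 21346 of the 21910 symbols of either table were found. Of the shared genes, 833 share exons with another gene. Scrublet called 57 of the 16282 cells, between 0.15% and 0.707% per library, a share too low for libraries of this size, so that leaving out its calls says little about doublets. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.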

Results

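Gene expression was measured cell by cell in neural tube organoids, which are hollow neuroepithelial structures grown from mouse embryonic stem cells. At day 6 some organoids had lengthened along an axis and others had not, and the labels call them elongated and non-elongated. The series holds 1 library of non-elongated organoids at day 6 and 2 of elongated organoids at day 6 (replicates 1 and 2). It holds 1 library each of elongated organoids at day 7, day 8 and day 10. No group other than elongated day 6 has replicates. The libraries held 2225 cells (non-elongated), 2076 and 2402 cells (elongated replicates 1 and 2), 2565 cells (day 7), 3337 cells (day 8) and 3677 cells (day 10). In the same order, the total UMI counts were 74072752, 77027668, 152742819, 133408217, 115735293 and 89832377. Median UMIs per cell ranged from 22053 at day 10 to 59014 in elongated replicate 2. The non-elongated library and elongated replicate 1 came in one table and the other libraries in another, so several list medians and genes are also given against the control of the same table, or with their level in each duplicate; the others are against both duplicates pooled. The genes named as highest or lowest in a comparison differed in the same direction from each duplicate.

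The comparison at day 6 asks how organoids that elongate differ from those that do not. In the non-elongated library more cells carried the authors' caudal epiblast and mesenchyme classes, and fewer carried the hindbrain and spinal cord classes, than in elongated replicate 1 of the same table. Caudal epiblast made up 45.6% of non-elongated cells (95% interval 43.5 to 47.7%) and 18.2% of elongated cells (16.6 to 19.9%), while anterior epiblast was the smaller share there, 5.39% (4.49 to 6.42%) and 9.54% (8.31 to 10.9%). In the non-elongated library the leading genes of that class included Otx2, En1 and Pax2, which also lead the midbrain class, so its name is given as deposited. The hindbrain class made up 22.7% (21.0 to 24.5%) and 35.6% (33.6 to 37.7%), and the spinal cord class 7.96% (6.86 to 9.16%) and 24.4% (22.6 to 26.3%); midbrain took like shares, 4.58% (3.75 to 5.54%) and 4.14% (3.33 to 5.09%). The mesenchyme class held 143 non-elongated cells, 6.43% (5.44 to 7.53%), and 17 elongated cells, 0.819% (0.478 to 1.31%). In the non-elongated library its leading genes included Mesp1 (123 CPM against 0.388 CPM in the other cells) and Eomes (44.7 against 0.532 CPM), transcription factors of early mesoderm. The class called surface ectoderm took 7.37% (6.32 to 8.54%) and 7.23% (6.15 to 8.43%) but held different cells: Sfn measured 393 CPM in it in the non-elongated library and 63.9 CPM in replicate 1, and Cldn4 241 and 24.7 CPM. Elongated replicate 2 was annotated in the other table with other class names, of which mid/hindbrain took 90.5% (89.2 to 91.6%) and none was called epiblast. In clusters made over all 6 libraries, the duplicates lay far apart, though replicate and table cannot be separated. A cluster led by Hox genes such as Hoxb9, in which most of the authors' spinal cord cells of the day 6 table lie, took 24.6% of replicate 1 and 3.25% of replicate 2, and clusters that no marker list named took 41.3% and 95.3%. The intervals cover counting error only.

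**Figure D1:**
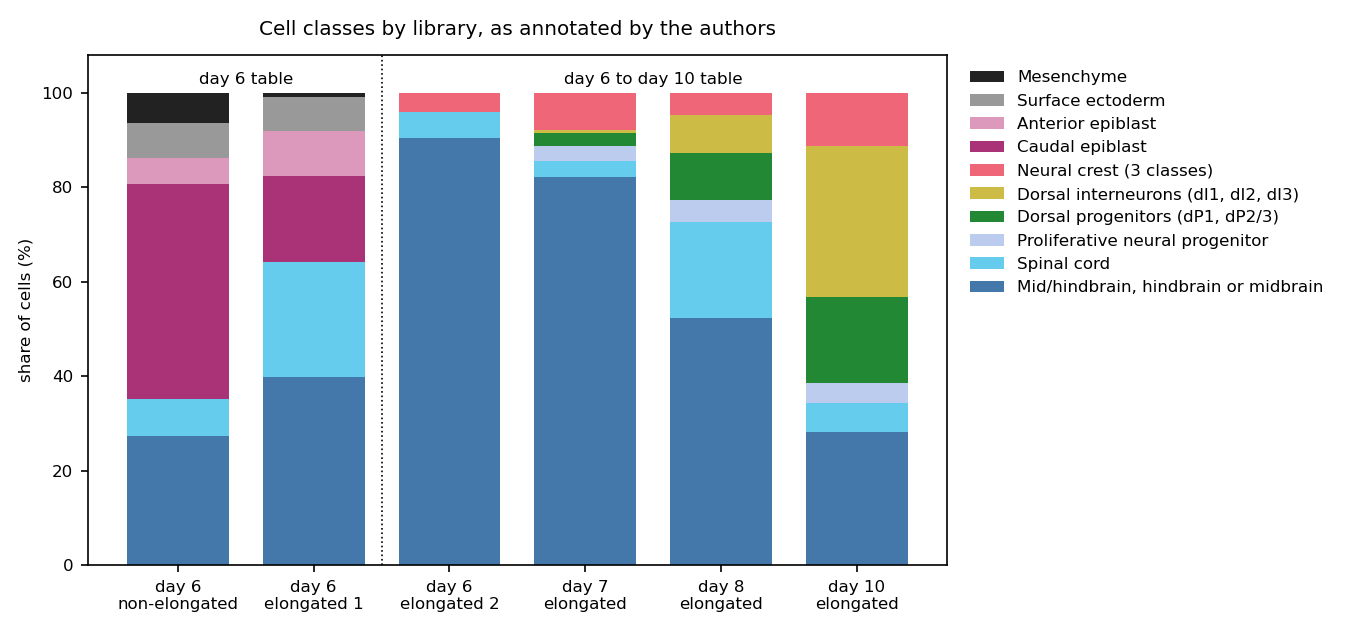
Share of cells (percent) in each of the authors' classes, 1 bar per library; a dotted line parts the 2 tables, which were annotated with different sets of classes. Caudal epiblast takes 45.6% of the non-elongated bar and 18.2% of the bar of elongated replicate 1, and neuron classes take 32.0% at day 10.

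Among the abundant genes farthest above the elongated libraries were several of epithelium, and among those farthest below several of neural progenitors, though none passed the test. Cldn4, a tight junction protein (chromosome 5, 134945119 to 134946934, mm10), measured 33.5 CPM in the non-elongated library against 3.31 and 1.37 CPM in the elongated replicates. Its log2 fold change was 3.85 ± 0.51 (SE; adjusted p 0.132), and 3.33 against replicate 1 alone. The claudins Cldn6 and Cldn7, the keratin Krt8 (376 against 103 and 35.0 CPM), Sfn, Hspb1, L1td1, Rspo3, Smagp and F2rl1 completed the higher genes, with log2 fold changes from 2.30 (F2rl1) to 3.44 (Sfn). Pax6, a transcription factor of neural progenitors (chromosome 2, 105668900 to 105697364), measured 4.92 CPM against 42.5 and 29.6 CPM. Its log2 fold change was −2.87 ± 0.35 (adjusted p 0.132), and −3.11 against replicate 1 alone. The nuclear receptors Nr2f1 and Nr2f2, the Notch effector Hes5, Meis1, Rfx4, Nrcam, Igfbp5, Fabp7 and Hist1h2ae completed the lower genes, from −1.89 (Meis1) to −2.30 (Nr2f2). Fabp7 and Hist1h2ae stood less far below replicate 1 (−0.89 each) than below replicate 2 (−2.65 and −2.61). The adjusted p-values of these 20 genes ran from 0.132 to 0.544.

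**Figure D2:**
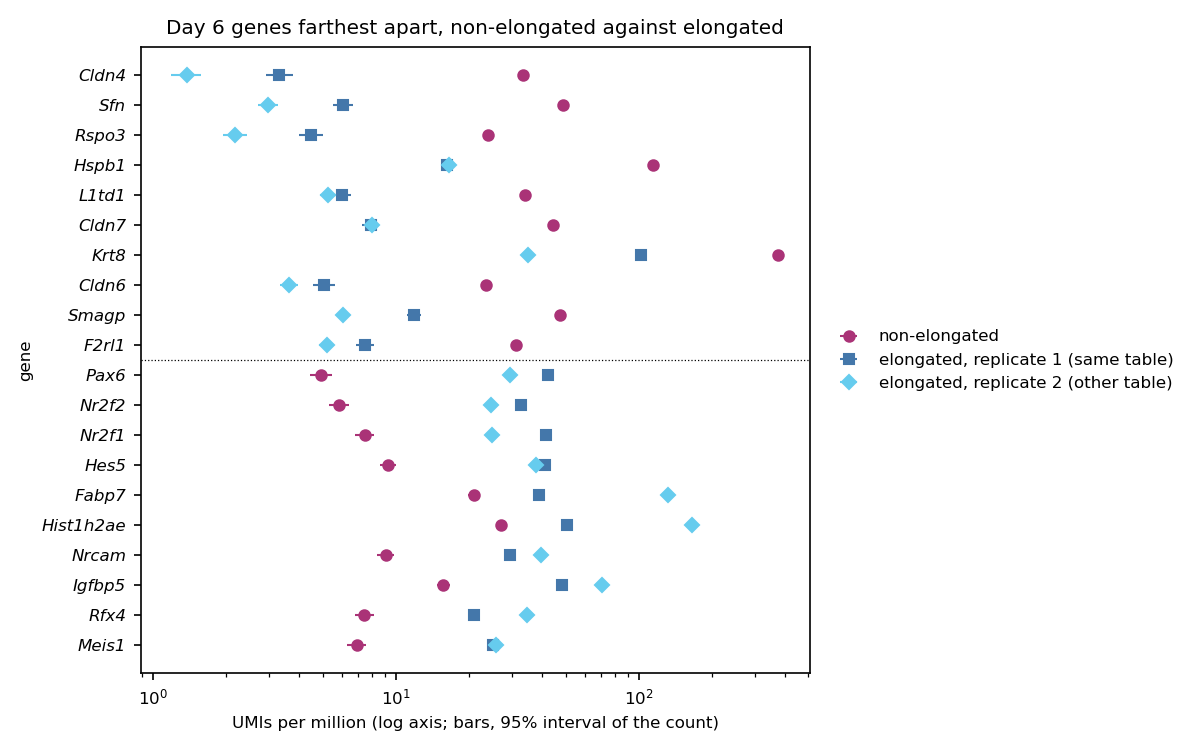
Expression (CPM, log axis) of the 20 genes named for the non-elongated comparison in the non-elongated library, elongated replicate 1 (same table) and elongated replicate 2 (other table), with 95% intervals of the count as bars. Cldn4 lies at 33.5 CPM in the non-elongated library and at 3.31 and 1.37 CPM in the elongated ones.

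Across gene lists, 0 members passed the test over all genes at day 6. Adjusted over the list alone, 6 of 7 surface ectoderm and epithelium genes were higher in the non-elongated library, with a list median log2 fold change of 2.13 (1.94 against replicate 1). Among them Epcam measured 224 against 68.0 and 54.3 CPM, and Cdh1, the epithelial cadherin, 44.9 against 11.7 and 9.91 CPM. Of the pluripotent and epiblast genes, 3 of 8 were higher adjusted over the list alone (median 1.86; 1.50 against replicate 1). Pou5f1, which maintains pluripotency, measured 234 against 59.3 and 52.5 CPM. FGF targets had 7 of 11 members higher adjusted over the list alone (median 1.27; 0.95 against replicate 1), with Spry4, a feedback inhibitor of FGF signalling, at 18.1 against 7.78 and 3.79 CPM. Neuromesodermal progenitor genes had 4 of 10 members higher (median 1.25; 0.86 against replicate 1), but on this list the median of replicate 2 over replicate 1 was itself −1.61. T, a mesoderm factor and 1 of the genes with a reporter in these cells, measured 6.58 against 2.23 and 0.517 CPM (adjusted p 0.558), Nkx1-2 37.8 against 17.8 and 7.95 CPM, and Tbx6 2.17 against 0.616 and 0.127 CPM. Neural progenitor genes had 5 of 9 members lower adjusted over the list alone (median −1.16; −0.89 against replicate 1). Sox1, the other reporter gene, measured 16.6 against 43.1 and 71.0 CPM (adjusted p 0.275), and Sox2 81.1 against 153 and 216 CPM. Retinoic acid pathway genes had 5 of 11 members lower (median −0.23), among them Rarb at 1.83 against 8.35 and 3.96 CPM. Of the muscle and heart genes 2 of 9 were higher adjusted over the list alone (median 1.94; 0.61 against replicate 1), and Hand1, a factor of lateral and cardiac mesoderm, measured 6.37 against 0.315 and 0.099 CPM.

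Cells with a UMI of both T and Sox2, the usual marks of neuromesodermal progenitors, were rare at 5000 UMIs per cell. They numbered 9 of 2225 non-elongated cells, 0.404% (0.185 to 0.766%), and 7 and 3 cells in the elongated replicates, 0.337% (0.136 to 0.693%) and 0.125% (0.026 to 0.365%). If the genes were detected independently, 0.828%, 0.321% and 0.240% would be doubly positive. In the non-elongated hindbrain class, which should lack T, 1 of 505 cells was doubly positive, 0.198% (0.005 to 1.10%), at a median depth before thinning of 33327 UMIs against 31906 over all non-elongated cells. At this depth the share over all cells lies within the interval of that background, which rests on 1 cell. Without thinning it does not: 6.07% of non-elongated cells (5.11 to 7.14%) carried both, with 7.55% expected, against 1.98% (0.954 to 3.61%) of the hindbrain class, with 2.20% expected. In the non-elongated spinal cord class, 5 of 177 cells carried both, 2.82% (0.923 to 6.47%), with 2.59% expected. T, with or without Sox2, was found in 16.8% of non-elongated mesenchyme cells and 0.594% of hindbrain cells. At day 7, 1 of 2565 cells carried both. At day 8 and day 10 there were 0 of 3337 and 0 of 3677 cells, which allows shares of cells detected at that depth of up to 0.09% and 0.082%; without thinning, 2 of 3337 and 0 of 3677 cells carried both. Cells with little T escape detection at either depth, so these limits do not hold for all cells that express both.

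With edgeR, 0 of 16379 genes were called between non-elongated and elongated organoids at day 6, and 1137 had an unadjusted p under 0.05. DESeq2 called 127 genes (58 higher, 69 lower). It gave no adjusted p-value to 2541 genes here, to 9796 within the neural progenitors, and to 1588 to 2858 over all cells at the later days. Its counts therefore cover fewer genes than those of edgeR. edgeR called 21 with RLE scaling and 10 without genes that share exons with another gene, a choice made after the data were seen. Leaving out replicate 1 sets the non-elongated library only against libraries of the other table. Calls of that fit, also within the progenitors, cannot be told apart from differences of table. At least 2-fold apart were 2142 genes, beside 1863 between the elongated duplicates; 1829 were 2-fold from replicate 1, of the same table. Within the neural progenitors 0 of 15789 genes were called by edgeR (522 with an unadjusted p under 0.05) and 11 by DESeq2, with 48 without replicate 1 and 0 without replicate 2. There, the list medians against both duplicates pooled were −0.61 for neural progenitor genes, 1.53 for pluripotent and epiblast genes and 1.89 for surface ectoderm and epithelium genes. These progenitors lay partly in different clusters made over all libraries. The largest cluster of replicate 2 (1478 cells) held 99.2% cells of that library, and 193 hindbrain cells of the day 6 table lay in clusters named as epiblast.

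The later days follow elongated organoids after day 6. At day 7, genes of epiblast and of caudal progenitors had fallen and genes of the dorsal neural tube had risen. Pou5f1 (chromosome 17, 35506018 to 35510772) fell from 59.3 and 52.5 CPM in the day 6 replicates to 1.90 CPM, 29.5-fold, with a log2 fold change of −4.88 ± 0.34 (adjusted p 0.00292) and −4.78 against replicate 2 alone. Nkx1-2, a factor of the caudal progenitor zone, fell from 17.8 and 7.95 to 0.067 CPM. Wnt8a fell from 28.1 and 69.1 to 0.341 CPM. In replicate 2, 9340 of the 9763 Wnt8a UMIs lay in the neural progenitors, of which 2173 of 2305 cells were mid/hindbrain. The fall of Wnt8a is therefore not read as a loss of caudal progenitors. Wnt1, a signal of the dorsal midline, rose from 5.33 and 2.18 to 63.0 CPM (log2 4.08 ± 0.48, adjusted p 0.00658). Gm32061 rose 55.1-fold, the netrin receptor Unc5c 30.2-fold and Casz1 13.5-fold. Epha2 fell 43.7-fold. Cdx2, a caudal homeobox gene, and the Hox cluster transcript Hoxaas3 also fell (log2 −8.32 and −5.29; −6.26 and −3.59 against replicate 2), from levels that differed between the duplicates (45.0 and 7.68 CPM for Cdx2, 143 and 26.2 CPM for Hoxaas3).

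By list, 10 of 15 genes of the dorsal progenitor domains rose at day 7 (12 adjusted over the list alone; median log2 2.41, and 2.58 against replicate 2), among them Zic1 (10.5-fold, to 126 CPM) and Atoh1 (from 0.055 and 0.142 to 3.06 CPM). Of the roof plate genes 4 of 7 rose (median 2.59), Rspo1 among them 4.96-fold. In the Notch pathway 4 of 12 rose (7 adjusted over the list alone; median 0.98), including Hes5 (3.56-fold) and Nrarp (3.25-fold). BMP targets had 2 of 10 risen members, Smad7 (5.17-fold) and Msx2 (from 4.93 and 1.06 to 36.9 CPM). Neural progenitor genes had 3 risen members of 9 (Nes 5.04-fold, Vim 4.16-fold, Hes5) and 1 fallen, Sox3 (4.19-fold). Sox1 measured 58.5 CPM, between the duplicates. In the neural crest list 2 of 10 rose, Tfap2b among them (from 0.383 and 0.142 to 9.46 CPM). Of the pluripotent and epiblast genes 6 of 8 fell (median −4.46), and of the neuromesodermal progenitor genes 5 of 10 (median −4.27; −3.58 against replicate 2). FGF targets fell in 8 of 11 members (9 adjusted over the list alone; median −2.98), Fgf8 63.2-fold and Dusp6 6.72-fold. Epithelial genes fell in 4 of 7 members (median −3.09, and −3.55 without Trp63, at 3 UMIs or fewer in both groups), Epcam 18.0-fold. In the retinoic acid pathway 4 of 11 fell and 2 rose; Cyp26b1, which breaks retinoic acid down, rose 5.93-fold. Ventral progenitor genes had 2 fallen members of 10, Nkx6-1 (20.7-fold) and Nkx6-2 (23.6-fold).

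Genes of hypoxia and glycolysis fell together at day 7, 12 of 16 over all genes and 16 adjusted over the list alone, with a list median of −2.05 (−1.95 against replicate 2). Ldha, which makes lactate, fell from 2506 and 1793 to 377 CPM (log2 −2.51 ± 0.32, adjusted p 0.00862), Pdk1 10.7-fold and Bnip3 8.33-fold. Beside them, 7 of 12 dissociation stress genes fell (10 adjusted over the list alone; median −1.72), with Egr1 falling 10.6-fold and Fos 4.99-fold. The median of replicate 2 over replicate 1 was −0.37 on the hypoxia list and −0.20 on the stress list.

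**Figure D3:**
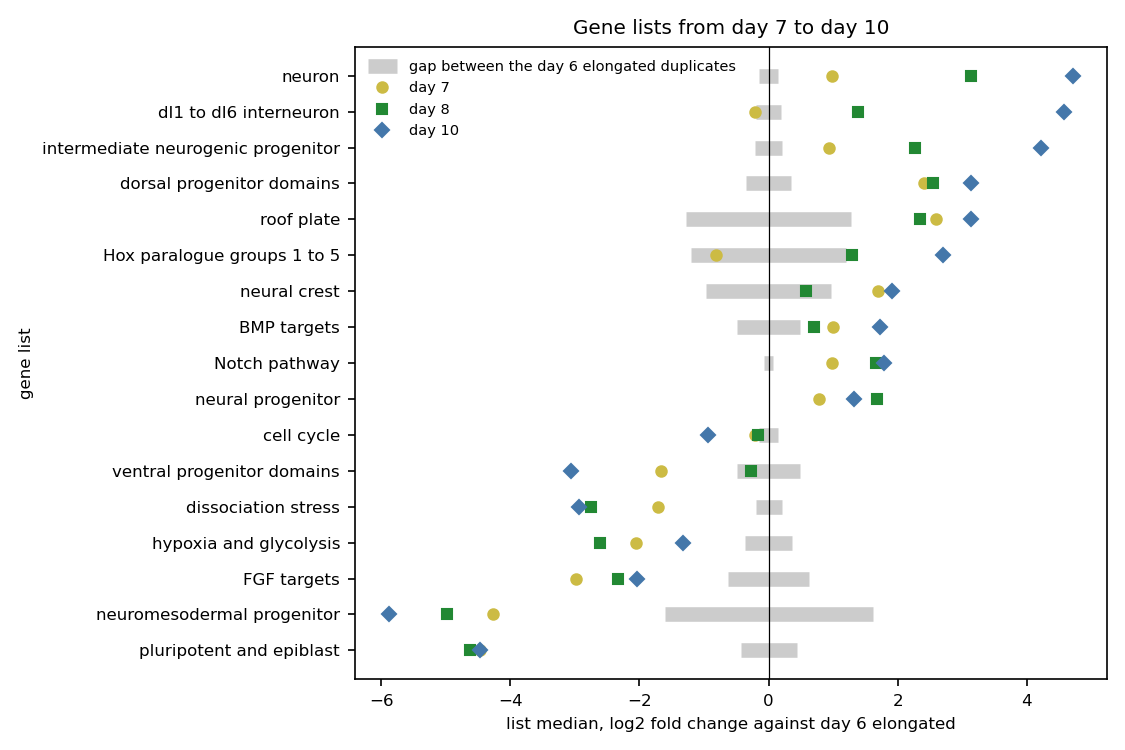
Median log2 fold change against day 6 elongated for 17 gene lists at day 7, day 8 and day 10, with grey bars for the gap between the day 6 elongated duplicates. The hypoxia and glycolysis list lies at −2.05 at day 7 and the neuron list at 4.71 at day 10.

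Among the authors' classes, neural crest took 7.80% of day 7 cells (6.79 to 8.90%) and 4.04% (3.29 to 4.90%) of elongated replicate 2, of the same table; in clusters made over all 6 libraries, that named as neural crest took 1.68% and 0%. Migratory cranial crest held 37 cells at day 7 (1.44%, 1.02 to 1.98%) and 0 of 2402 at day 6, which allows up to 0.125%. The crest classes were not all led by crest genes. The leading genes of the Pre-EMT cranial class at day 6 included Sfn, Krt8 and Cldn4, of epithelium, beside Tagln and Meox1, of mesenchyme and mesoderm, and at day 7 it held Epcam, Krt8 and Rspo1 among its leading genes. The vagal and trunk class was led at day 6 by Cdx2 and Hoxb8, of caudal progenitors. The class called dP2/3, led at day 7 by Tfap2b, Cck and Tlx3, genes more of newborn neurons than of progenitors, held 67 cells at day 7, 2.61% (2.03 to 3.31%), and 1 cell at day 6, 0.042% (0.001 to 0.232%). With edgeR, 654 of 16379 genes were called at day 7, 312 higher and 342 lower, and 980 by DESeq2; scaling by library size alone turned the balance to 340 higher and 269 lower. With a minimum count of 100, 380 were called. At least 2-fold apart were 3420 genes (3299 against replicate 2 alone), beside 1863 between the duplicates. No single day can be tested without a duplicate; a slope over day called 3791 genes with all libraries, 1640 without replicate 1 and 431 without replicate 2.

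By day 8, genes of neurons had risen. Dcx, which marks young neurons, rose from 0.233 and 0.382 to 48.2 CPM, 157-fold (log2 7.24 ± 0.35, adjusted p 0.000205). Nhlh2, a factor of newborn neurons, rose from 0.041 and 0.042 to 38.5 CPM (log2 9.80 ± 0.34, adjusted p 9.59e-05). Neuron genes rose in 10 of 11 members (median 3.14; 3.45 against replicate 2), Map2 29.3-fold and Elavl3 17.6-fold. Intermediate neurogenic progenitor genes rose in 9 of 10 (median 2.27), Insm1 among them 43.2-fold, and 6 of 9 neural progenitor genes rose (median 1.68), Vim 14.3-fold and Nes 7.80-fold. C130071C03Rik, D930028M14Rik, the transcription factor Tfap2b and Gm32061 stood with Nhlh2 as the highest genes, with log2 fold changes of 10.51, 7.71, 7.38 (6.68 and 8.01 against replicates 1 and 2) and 7.35. Dorsal interneuron genes were divided, with 9 of 18 risen and 4 fallen; Tlx3, a factor of sensory relay interneurons, rose 42.6-fold. In the Notch pathway 7 of 12 rose, Nrarp 8.39-fold and Dll3 7.66-fold.

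The lowest genes at day 8 were Cdx2 (0 CPM, at least 1045-fold lower, and at least 1786-fold and 304-fold against replicates 1 and 2), Wnt8a (log2 −8.58; −7.60 and −8.90 against the replicates), Egr4 (−7.48; −8.17 and −4.57), Klf2 (−6.66) and Slc16a3. Slc16a3, which exports lactate, fell from 213 and 192 to 2.19 CPM (log2 −6.53 ± 0.37). Hypoxia and glycolysis genes fell in 14 of 16 members (median −2.61), Ldha 16.2-fold to 133 CPM and the glucose transporter Slc2a3 28.0-fold. Dissociation stress genes fell in 10 of 12 (median −2.76). FGF targets fell in 9 of 11, pluripotent and epiblast genes in 7 of 8 with 1 risen, and neuromesodermal progenitor genes in 7 of 10. WNT targets had 7 fallen members of 14 and 2 risen, with Cdx1 falling 150-fold and Dkk1 from 5.22 and 10.6 to 0.303 CPM. Forebrain and midbrain genes fell in 3 of 13 (median −2.25), Otx2 from 5.97 and 0.743 to 0.076 CPM (78.9-fold and 9.82-fold).

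Neuron classes held 8.15% of day 8 cells (7.25 to 9.13%), against 0.585% (0.328 to 0.963%) at day 7 and 0 of 2402 cells at day 6, which allows up to 0.125%. The spinal cord class took 20.3% at day 8 (18.9 to 21.7%), 5.45% (4.58 to 6.44%) in replicate 2 at day 6, 3.35% (2.69 to 4.12%) at day 7 and 6.20% (5.44 to 7.03%) at day 10. edgeR called 2192 genes at day 8, 1104 higher and 1088 lower, and DESeq2 2348. Scaling by library size alone leaves out the TMM factors, which raises log2 values at once by 0.114 at day 7, 0.137 at day 8 and 0.252 at day 10. It turned the day 8 split into 1337 higher and 907 lower. At least 2-fold apart were 4923 genes (4759 against replicate 2 alone), beside 1863 between the duplicates. The slope over day gave 431 genes without replicate 2, against 3791 with all libraries.

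At day 10, many of the genes highest above day 6 were neuronal. Nhlh2 (chromosome 3, 102010076 to 102015492) rose to 256 CPM (log2 12.53 ± 0.36, adjusted p 2.31e-05). Dcx (chromosome X, 143855842 to 143933311) rose 758-fold to 233 CPM (log2 9.52 ± 0.38, adjusted p 7.13e-05; 9.18 against replicate 2 alone). Tubb3, the neuronal tubulin, rose 50.1-fold to 779 CPM (log2 5.65 ± 0.39, adjusted p 0.000182). The neuron list rose in 11 of 11 members (median 4.71; 4.96 against replicate 2), and the list of intermediate neurogenic progenitors in 9 of 10 (median 4.22). Also among the highest genes were the glutamate receptor subunit Gria2, the sodium channel Scn3a, the neuropeptide precursor Cartpt, the synuclein Sncg, the microRNA host Mir124a-1hg and Tfap2b, C130071C03Rik and D930028M14Rik, with log2 fold changes from 8.88 (Tfap2b; 8.18 and 9.51 against replicates 1 and 2) to 11.98 (C130071C03Rik). Transmitter and synapse genes rose in 7 of 10 (median 2.71), Syt1 93.9-fold and Snap25 7.42-fold.

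**Figure D4:**
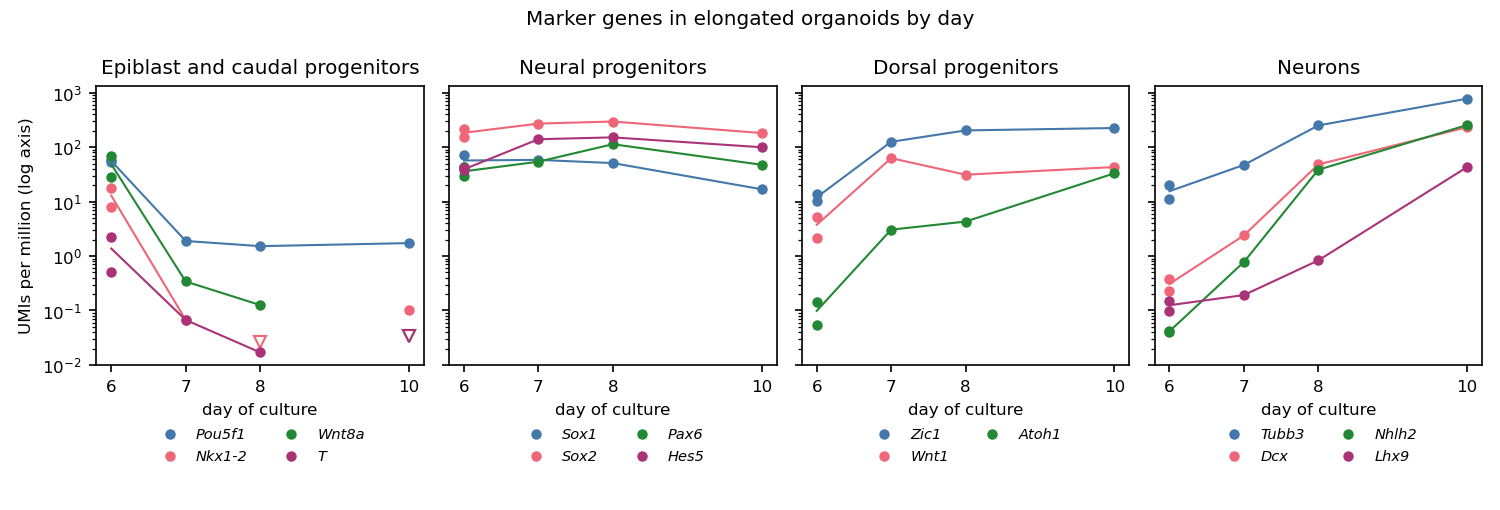
Expression (CPM, log axis) by day for caudal and pluripotent genes with Wnt8a beside them, neural progenitor genes, dorsal progenitor genes and neuron genes in elongated organoids. At day 6 both replicates are points and lines start at their mean. Open triangles mark the floor of 3 UMIs where the count was 0. Dcx climbs to 233 CPM at day 10, while Wnt8a ends at 0 CPM.

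Genes of dorsal interneurons and dorsal progenitors rose at day 10, and several of the ventral progenitor genes fell. Dorsal interneuron genes rose in 12 of 18 members (median 4.58, and 4.77 with genes at 0 UMIs set to their bound), with Lhx9 rising 346-fold to 43.2 CPM, Barhl1 381-fold and Lhx1 39.5-fold. Dorsal progenitor genes rose in 11 of 15 (14 adjusted over the list alone; median 3.14), Atoh1 from 0.055 and 0.142 to 33.2 CPM and Gsx2 85.4-fold, and roof plate genes in 5 of 7 (median 3.14). Ventral progenitor genes fell in 6 of 10 with 2 risen (median −3.06, and −2.66 with bounds): Dbx2 fell 107-fold, Nkx6-1 15.8-fold, and Dbx1 from 11.1 and 1.56 CPM to 0. Olig2, a ventral factor, measured 0.370 CPM against 0.192 and 0.142 CPM (adjusted p 0.262). Motor neuron genes had 3 risen members of 11 (median 0.37), Isl1 (from 0.575 and 0.276 to 3.58 CPM) and Lhx3 among them, while Mnx1 measured 0.06 CPM against 0.356 and 0.255 CPM. Neural crest genes rose in 5 of 10 (median 1.92); Sox10 rose from 0.726 and 0.311 to 8.21 CPM (log2 4.01 ± 0.56, adjusted p 0.00266). Peripheral neuron genes rose in 4 of 7 (median 3.79), Pou4f1 among them 17.4-fold.

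The authors' dorsal interneuron classes dI1, dI2 and dI3 held 11.8% (10.8 to 12.9%), 10.2% (9.21 to 11.2%) and 9.98% of day 10 cells, together 32.0% (30.5 to 33.5%). In dI1, Lhx9 measured 396 CPM against 8.84 CPM in all other day 10 cells, and Barhl2 123 against 6.23 CPM. In dI2, Pax2 measured 86.2 against 1.54 CPM and the inhibitory transmitter transporter Slc32a1 64.3 against 0.836 CPM; the genes leading this class are largely those of inhibitory neurons, so its name and share are given as deposited. In dI3, Phox2a measured 203 against 0.876 CPM and Calb2 200 against 2.92 CPM. Atoh1 led in the progenitor class dP1 (310 against 20.3 CPM), and Neurog2 and Ptf1a led in dP2/3. Migratory cranial crest carried Sox10 (374 against 0.581 CPM) and Npy. The class called Pre-EMT cranial neural crest, 6.94% of day 10 cells (6.13 to 7.80%), carried Sox10 at 0.125 CPM. These classes were drawn by the authors on the same cells, so their leading genes are not independent evidence of identity.

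The lowest genes at day 10 were Wnt8a (chromosome 18, 34542313 to 34548273), at 0 CPM and at least 1618-fold lower (adjusted p 0.000351; at least 936-fold and 2301-fold against replicates 1 and 2), and Cdx2, at least 878-fold lower (at least 1500-fold and 256-fold). Ifitm1, the Hes family repressor Hes3 and Klf2 fell 167-fold, 136-fold and 110-fold, and Sp8 and the junction protein F11r 90.9-fold and 84.3-fold; Spint1 and Fosb also fell. Egr4 fell 236-fold, but 437-fold against replicate 1 and 35.7-fold against replicate 2. T fell to 0 CPM (at least 45.8-fold lower, adjusted p 0.00854; at least 74.3-fold and 17.2-fold against the replicates). Sox1 fell 3.38-fold to 16.9 CPM (log2 −1.76 ± 0.37, adjusted p 0.0131), while Sox2 and Pax6 measured 182 and 47.6 CPM (log2 −0.02 and 0.40, adjusted p 0.972 and 0.347). Cell cycle genes fell in 9 of 18 members (median −0.95), Mcm5 3.31-fold and Mcm3 2.88-fold. Hypoxia and glycolysis genes fell in 10 of 16 (median −1.32), with Ldha at 649 CPM, and dissociation stress genes in 10 of 12 (median −2.93). In Hox paralogue groups 1 to 5, 9 of 15 genes rose and 2 fell (median 2.71): Hoxd3 rose from 1.23 and 2.51 to 20.4 CPM and Hoxa2 2.62-fold, and Hoxb1 fell 14.4-fold. Of groups 6 to 9, 1 of 11 genes rose, Hoxa6 (from 0.082 and 0.021 to 2.26 CPM). Their median of 0.92 became −0.67 without replicate 2 and 2.36 without replicate 1. edgeR called 4320 genes at day 10, 2302 higher and 2018 lower, and DESeq2 4129; scaling by library size alone gave 2991 higher and 1382 lower. At least 2-fold apart were 6422 genes (6141 against replicate 2 alone), beside 1863 between the duplicates. The slope over day, in place of a test of day 10 alone, called 1640 genes without replicate 1 and 431 without replicate 2.

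Within the cells the authors class as neural progenitors, neurogenic and dorsal genes had also risen at day 10. Atoh1 rose from 0 and 0.146 CPM at day 6 (log2 8.99 ± 0.80, adjusted p 0.000698), Barhl1 407-fold to 33.1 CPM and Nhlh1, a factor of newborn neurons, to 23.3 CPM. Nhlh2 reached 73.1 CPM and C130071C03Rik 160 CPM from 0 and 0.022 CPM. Intermediate neurogenic progenitor genes rose in 9 of 10 members (median 4.46), dorsal progenitor genes in 12 of 15 (median 2.75) and neuron genes in 8 of 11 (median 2.37). Among the lowest genes, Wnt8a was at least 779-fold lower (at least 304-fold and 1253-fold against replicates 1 and 2) and Egr4 fell 317-fold (590-fold and 44.1-fold). Ifitm1 fell 391-fold, the sulfatase Sulf1 226-fold and F11r 164-fold. Hypoxia and glycolysis genes fell in 9 of 16 (median −1.04) and dissociation stress genes in 10 of 12 (median −2.95). Cell cycle genes had 2 risen and 2 fallen members of 18 (median −0.39). This group holds 1333 and 2305 cells of the day 6 replicates and 2085 of day 10, and its day 6 members were named differently in the 2 tables. At day 10, dP1 and dP2/3 held 270 and 394 of its cells, against 0 and 1 in replicate 2. The rises in this group thus cannot be told apart from the arrival of these classes. In the clusters made over all libraries, 181 of 313 dP1 cells of the later table lay in clusters named as neurons, and clusters named as neural progenitors held 0 of 2402 cells of replicate 2. The rise in neuron genes is thus within a group whose cells lie in different clusters at the 2 days. edgeR called 2698 of 15789 genes (1397 higher, 1301 lower) and DESeq2 2696; scaling by library size alone gave 1658 higher and 918 lower. A slope over day within these cells called 83 genes without replicate 1 and 1 without replicate 2.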

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

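The tests of exon sharing, of the mix of classes within single classes, of handling, of the choroid plexus profile and of doublets made only of other day 10 classes were chosen after the results they measure were seen.

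4 genes present only in the table of the later days had 0 UMIs in elongated replicate 2, the control of that table, and at least 10 CPM at day 10, a signal outside the genes compared above. St18, a transcription factor, measured 14.3 CPM at day 10, at least 729-fold over the floor of 3 UMIs, and was highest in the dI1 class (50.6 CPM). Ppp1r17 measured 13.5 CPM, at least 686-fold over that floor, with 40.4 CPM in dI1 and 40.1 CPM in dI3. Gm32849 measured 12.8 CPM, at least 650-fold, with 30.4 CPM in dP1. Ttr, which encodes transthyretin, measured 12.2 CPM, at least 621-fold, and 1077 of its 1096 UMIs lay in the class called Pre-EMT cranial neural crest.

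The day 6 elongated duplicates were far apart for some abundant genes: of 5639 genes at 20 CPM or more in either, 67 differed at least 4-fold, 44 of them higher in replicate 2. After thinning to the shallowest library, 98.5% of the 67 stayed 4-fold apart. Thinning hardly changes such ratios at 20 CPM or more, so this result was near fixed in advance and says little about depth. All 67 (100.0%) were at least 2-fold apart the same way within the neural progenitors, but this group keeps a mix of its own, with 507 of 1333 cells in the spinal cord class in replicate 1 and 131 of 2305 in replicate 2, and decides nothing. Counting against different gene annotations may account for part: 28 of the 67 share exons with another gene (41.8%), against 246 of the other 5572 (4.41%), an odds ratio of 15.5 (Fisher exact test, two-sided p 4.64e-20). A different mix of classes is argued against for these 28, since 100.0% stayed at least 2-fold apart the same way within the spinal cord class and within the mid and hindbrain classes. Of the 39 that share no exons, 76.9% did so, 30 genes with Ptp4a1 among them (118 CPM in replicate 1 and 1.27 CPM in replicate 2). The other 9 did not: Cdx2, Hoxa7, Hoxb5os, Hoxb8, Hoxb9, Hoxc8, Hoxaas3, Lmna and Tnfrsf12a. Hoxb9 measured 114 and 20.8 CPM over all cells but 382 and 276 CPM within the spinal cord class, so a different mix may account for part of these 9. For the 39, the labelled batch, the table and biological variation between batches cannot be told apart, because the replicates carry different batch labels and lie in different tables. Exon sharing was judged in GENCODE vM21 alone, so different annotations stay open for the 39 as well.

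Hypoxia and glycolysis genes fell at day 7, with Ldha, Pdk1 and Bnip3 among 12 of 16 members. A change in the mix of the authors' classes is argued against by the spinal cord class (131 cells in replicate 2, 86 at day 7). Within it the list median of day 7 against replicate 2, of the same table, was −1.55, beside −1.71 over all cells. The list median was 103% of the all-cell value within neural progenitors, and 101% (−1.74, lower in 16 of 16 members) within mid/hindbrain. These 2 percentages decide little, since mid/hindbrain alone made up 90.5% of replicate 2 and 82.2% of day 7. A change of cells within a class was not tested. In clusters made over all 6 libraries, the largest of replicate 2 and of day 7 held 99.2% and 98.5% cells of their own library. Handling at dissociation could lower these genes together with the stress genes, which fell as well, and cannot be told apart from the day: from day 8 to day 10 the members' median change was 1.13 for the hypoxia list but 0.07 for the stress list, less than the gap between the duplicates (−0.20). The day itself, and the move of organoids to fresh Matrigel after day 6 that goes with it, stay open as untested explanations. All 3 later libraries share these conditions, so no library separates them.

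The class called Pre-EMT cranial neural crest (255 cells at day 10) was low in neural crest genes (median log2 ratio to the other day 10 cells −1.69) and high in roof plate genes (2.88), with Wnt1 at 183 CPM against 35.0 CPM, though another day 10 class was higher for 4 of the 8 measured roof plate genes (Lmx1a, Msx1, Msx2 and Bmp6; Msx1 233 against 513 CPM), and Ttr at 135 CPM against at most 0.867 CPM in any other class. Its profile may be that of choroid plexus and roof plate: the median over the 11 measured of 12 choroid plexus markers, 3 of which stand in other lists, was 1.05, with 6 members above 2-fold, Otx2 (51.8 CPM) among them. That median is the value of Sostdc1, which measured only 1.63 CPM (13 UMIs) in the class. Other members were near the floor too, with Aqp1, Kl and Cldn2 at 0, 1 and 4 UMIs there. Ttr, which stood out beforehand, is itself a member of the list. Doublets stay open too: the class had 1.31 times the library's median UMIs (28865 against 22053), barely past the bound of 1.3. Depth alone does not decide it, since the other classes outside the neurons had medians from 16549 (dP2/3) and 18895 (dP1) over 23243 (spinal cord), 25975 (mid/hindbrain), 26756 (vagal and trunk crest) and 27476 (proliferative progenitors) to 35936 (migratory crest). For doublets made only of other day 10 classes, the choroid plexus markers' median against the highest other class was −0.26, on the doublet side of its bound. Yet members went both ways: Ttr and Otx2 lay far above every other class and Enpp2 (4.76 CPM against 174.8 CPM) far below. A count over abundant markers of the choroid plexus and roof plate lists together was also tried. It put 2 of 8, Ttr and Otx2, more than 2-fold above every other class. Neither explanation is excluded, and no biological explanation beyond them was tested.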

How the results depend on the processing

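Of the summary results under all alternatives, 150 stayed within their bounds and 43 moved. Of the list medians, 605 stayed, 146 moved and 5 changed sign among lists in the outer 5% of random lists (28 sign changes over all lists). Of the values of named genes, 1104 kept their side of the threshold, 52 newly passed it and 107 no longer passed it. For 1 the sign changed with the threshold passed in either fit. Sign changes of genes that passed in neither fit count among the 1104. The alternatives without genes that share exons, with renamed symbols joined, with progenitors and epiblast together, and all those for the non-elongated comparison within progenitors were chosen after seeing the data. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Leaving out a duplicate leaves no residual degree of freedom with a mean per group. These fits therefore test a slope over day, with the lone library assumed to vary like the others. Without replicate 1, the non-elongated library and all elongated ones lie in different tables. No value could be had for class shares without a duplicate. A further cell filter (at least 2000 genes, at most 10% mitochondrial UMIs) removed 0 cells. It could remove none, since the deposited cells had passed tighter bounds. Depth limits what shares of 0 mean and the count of T and Sox2.

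For genes called between non-elongated and elongated day 6 organoids (0), the count was 127 with DESeq2, 21 with RLE scaling, 10 without genes that share exons and from 0 to 43 without a duplicate; within progenitors (0) it was 11 with DESeq2 and from 0 to 48 without a duplicate. A minimum count of 100 gave 380 at day 7 (654). The linear term, which tests a slope over all days with 3 residual degrees of freedom, gave 3791 at day 7 (654) and day 8 (2192). Without a duplicate, day 7, day 8 and day 10 (4320) gave from 431 to 1640 and day 10 progenitors (2698) from 1 to 83. Genes at least 2-fold apart numbered 1127 with a minimum count of 100 and 1363 with a prior count of 10 for non-elongated against elongated (2142), 957 and 1144 between the duplicates (1863), and 2266 with a minimum count of 100 at day 7 (3420). Except where a cause is given, the cause was not tested.

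With clusters made over all 6 libraries and named by lists, epiblast took 62.3% of the non-elongated library (51.0% by the authors' classes) and 20.4% of elongated replicate 1 (27.7%), and surface ectoderm 3.33% (7.37%) and 13.1% (7.23%). Neural progenitors took 0% of the non-elongated library (35.2%), 0% and 0% of elongated replicates 1 and 2 (64.2% and 96.0%), 2.53% at day 7 (91.6%), 79.2% at day 8 (87.3%) and 43.1% at day 10 (56.7%); neural crest took 0% of replicate 2 (4.04%), 1.68% at day 7 (7.80%), 0.21% at day 8 (4.56%) and 1.55% at day 10 (11.3%). Clusters that no list named took 23.5%, 41.3% and 95.3% of the day 6 libraries and 61.8% at day 7, so the naming rule accounts for part. It also misplaced clusters: that named surface ectoderm was led by Dusp2, Hbegf and Lmna, while 187 cells led by Sfn, Cldn4 and Krt8 stayed unnamed, and 392 cells led by En1 and Otx2, of midbrain, counted as epiblast. The reversed order of surface ectoderm is therefore not relied on. At 2500 UMIs per cell, cells with both T and Sox2 made up 0.09% (non-elongated), 0.048% and 0% (elongated replicates 1 and 2) and 0% (day 7); unthinned they made up 6.07%, 3.95%, 2.54% and 0.234%, which follows depth by construction. Without a duplicate, the list medians ran from −0.089 to 1.07 for Hox groups 1 to 5 (0.21) and from −0.52 to 2.15 for groups 6 to 9 (0.77) in the non-elongated comparison, from −0.44 to 2.51 for groups 6 to 9 at day 8 (1.03), negative without replicate 2. The cause was not tested. For Sox1 at day 7 (0.04) the fits gave slopes per day from −0.52 to −0.39, which are not the change at day 7: that was 0.44 against replicate 1 and −0.28 against replicate 2. A minimum count of 100, which drops members, changed the sign at day 10 of floor plate (−1.92 to 0.24) and of forebrain and midbrain (−1.49 to 1.05).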

Other observations

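Genes of adhesion and of regional identity changed beside those described above. Cdh1 fell at day 7 to 0.466 CPM, 23.2-fold, while the mesenchymal cadherin Cdh11 rose 6.14-fold at day 7 and 16.2-fold at day 10 (to 51.5 CPM), and Cdh2, the neural cadherin, rose 1.87-fold at day 10 (adjusted p 0.0349). The list of extracellular matrix and adhesion genes had 2 risen and 3 fallen members of 14 at day 10 (median log2 0.21). Hindbrain genes had 3 risen and 4 fallen members of 9 at day 10 (median −0.15): Egr2, a factor of rhombomeres, fell 44.2-fold and Fgf3 24.4-fold. At day 7 several genes of dorsal interneurons lay lower than at day 6, with 5 of 18 fallen and 1 risen (median −0.21, and −0.33 with genes at 0 UMIs set to their bound); Lhx5 fell from 5.27 and 6.23 to 0.118 CPM, Phox2a 22.2-fold and Pax2 8.25-fold. In the planar polarity and tube shaping list, 4 of 17 rose and 2 fell at day 10 (median 0.10), with Fzd3 rising 3.18-fold and Ror2 falling 9.73-fold. In the non-elongated comparison 0 of 17 were called, and the median was −0.08.

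Genes of glia and late progenitors rose in 7 of 13 members at day 10 with 1 fallen (median 1.35). Nfib, a factor of the switch to gliogenesis, rose from 0.301 and 0.382 to 42.3 CPM, 124-fold, and Nfia 36.6-fold to 56.1 CPM. Response genes of p53 fell in 7 of 11 members with 1 risen at day 10 (median −1.04), Phlda3 8.72-fold and Ccng1 2.41-fold. In the SHH pathway 2 of 8 rose and 2 fell at day 10 (median −0.10), with Gli1 falling 17.5-fold from 0.835 and 0.913 CPM and Cdon rising 2.56-fold. The vagal and trunk crest class of day 10 (105 cells, 2.86%, 2.34 to 3.45%) was led by Col14a1 (479 CPM against 3.68 CPM in the other day 10 cells) and carried Aldh1a2, which makes retinoic acid, at 147 against 1.37 CPM. No gene of the neural crest list was among its 10 leading genes, and over replicate 2 and the later days its cells lay mostly in clusters named as neural progenitors or roof plate (91 cells in the latter) and none in that named as neural crest. The class of proliferative neural progenitors (158 cells, 4.30%, 3.67 to 5.00%) carried Insm1 at 381 against 62.4 CPM and the mitotic gene Nusap1 at 511 against 123 CPM.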
